A study of Clostridium carboxidivorans with 8 samples.

How the data were processed

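Total RNA of Clostridium carboxidivorans, an anaerobic bacterium that fixes CO and CO2 into acids and alcohols, was measured on 8 custom Agilent arrays with a single dye, Cy3. The cultures were grown in 30 mL of inorganic medium. In 4 cultures the electron donor was iron granules, at 1 g per 10 mL, and the other 4 received syngas, a gas mixture, and no iron. Per the labels' protocols, cells were broken by bead beating, RNA was treated with DNase on a column, and labelled cRNA was made with a low-input whole-transcript labelling kit. Per the series design, the experiments used separate cultures. Groups and replicate numbers were taken from the sample titles.

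Each array file holds spot intensities that, per the file headers, came from Agilent Feature Extraction 11.5.1.1. The submitters' processing notes name version 9.1 of that program. The processed intensity deposited for each spot was background-subtracted and detrended across the array surface, per the file headers, and had no scaling between arrays. The deposited files also hold the median pixel intensity of each spot, its local background and flags for outlying, saturated and well-above-background spots. The authors' value table is on a log2 scale: within each array its gene values equalled log2 of the processed intensity minus 1 constant, to within 1.3e-06 log2 units, and its columns had 75th percentiles between -0.001 and 0 and medians between -2.18 and -2.07. Its genes were therefore neither centred nor quantile-normalized, and its direction is that of signal. All 8 arrays were on 1 slide, with the 4 iron arrays in one row and the 4 syngas arrays in the other, per the file headers. Slide row and electron donor cannot be told apart. The syngas cultures also had no iron, so the donor cannot be told apart from other effects of the iron or of the gas.

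An array had 15524 spots, of which 14988 were gene spots and 536 were controls. The gene spots came from 14898 probes for 4951 gene identifiers, with 3 probes for 4936 genes and 6 for 15. For 4948 genes the identifier is a pair of numbers, such as 01065_211; the last part is a running number from 1 to 4951, and the first part rises with it throughout. The order of the running numbers was taken as gene order. The other 3 identifiers carry the name of a separate sequence. The files do not pair identifiers with gene products, and no table of products or genome was used here. The lists of pathways fixed from product names therefore could not be formed, and genes are reported by identifier.

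From the intensities, control spots and spots flagged as outliers were left out (1 to 12 flagged gene spots per array; no gene spot was saturated). The log2 processed intensity minus the array's 75th percentile over gene spots was taken, repeated spots were averaged, 18 probes with a flagged single spot were dropped, and the mean over a gene's probes was its value. A gene was measured if at least 1 probe was well above background on at least 4 of the 8 arrays; 4048 genes passed and 903 did not. Iron was compared with syngas with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over the 4048 genes and a threshold of 0.05. Differences are log2, iron minus syngas. Folds that rest on dim signal are also given against a floor, as lower bounds where the bright group is itself above background. This sets the bright group's mean against the dim group's mean of, per probe and array, the higher of the array's lowest signal among probes well above background and the probe's own signal. The bright group is not raised to a floor, so where its own probes are dim the value is no bound. The floor is set per array, so it can differ between the groups. A run was at least 4 genes with consecutive running numbers that all passed the threshold, changed at least 2-fold and moved the same way; genes that were not measured ended a run. Runs were compared with 1000 random placements of the calls along the measured genes.

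The fit was tested on simulated data made from the means and spreads of the 4048 genes. For iron against syngas, the fit recovered 4% of 50 genes changed 1.5-fold and 38% of 50 changed 2-fold. It recovered 86% of 50 changed 4-fold and 100% of 50 changed 8-fold, and called 5 of 3848 unchanged genes. Only these 4 sets of 50 genes were changed, with errors independent between genes and between arrays. In the data far more genes were called and neighbouring genes changed together, so these rates do not carry over to the real comparison. The number of arrays, 4 per group, limits the precision, and p-values measure the spread between these arrays. Per the series design the cultures were separate. The iron arrays formed close pairs, however, and the same labelled RNA on both arrays of a pair was not excluded, as described below. It is therefore not established that the spread among iron arrays is that between cultures.

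Tests, filters, run rule and the rule for named genes were fixed before the data were examined. That rule named, first, the genes with the largest changes that passed the threshold, changed at least 2-fold, had no overlap between the groups and were above background on all arrays of a group. Without product names, 2 genes in each direction are named, and longer runs are described without their identifiers. The results were also computed with quantile and median scaling, normexp background correction, a looser and a stricter filter, the brightest probe per gene, the replicate number as a block, a trended and robust spread, the authors' processed values, a stricter threshold, a test against 1.5-fold and leaving out each array. The normexp correction used the median spot intensity, since the files hold no mean intensity column. It also added an offset of 50 to every spot. For comparison, the 75th percentile of processed intensity was 47.0 to 96.4 on syngas arrays and 122 to 266 on iron arrays. An offset of that size shrinks the folds of dim genes and, after scaling, sets dim genes lower on iron. Scaling to 6 E1A probes and averaging of close pairs of iron arrays were added after the data were seen. E1A probes are Agilent's control probes for spike-in RNA; the protocols do not mention the step at which such RNA was added, so it is not known whether equal amounts went into each sample. Of the 10 E1A probes the 6 brightest were used, a choice made by hand; 7 were above background in every spot of every array, and the log2 difference between iron and syngas was 0.49 over these 7 and 0.48 over the 6.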

Results

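Arrays with probes for 4951 genes of C. carboxidivorans, of which 4048 were bright enough to be measured, were hybridised with RNA of 4 cultures with metallic iron granules as electron donor and 4 cultures on syngas, all sampled in log phase. The design asks which genes differ when the bacterium draws on iron in place of gas. Gene signal was stronger on the iron arrays. The 75th percentile of gene spot intensity was 194 ± 69.7 (SD, n = 4) for iron and 62.6 ± 23.1 (SD, n = 4) for syngas, with ranges of 122 to 266 and 47.0 to 96.4. The log2 difference was 1.62, and the groups did not overlap (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 allows). Gene spots well above background made up 75.8% ± 3.84 (SD, n = 4) on iron arrays and 59.5% ± 5.28 (SD, n = 4) on syngas arrays (two-sided exact permutation p = 0.0286). The 6 spike-in probes differed less, by 0.48 log2 units, with overlap between the groups (two-sided exact permutation p = 0.0857, n = 4 per group). All differences below are relative to the 75th percentile of each array, so a shift common to most genes is not seen in them. Negative control spots read 1.80 to 2.59 on iron arrays and 1.56 to 2.04 on syngas arrays. On the scaled values, signal at background therefore lies lower on iron, which can make dim genes look lower there. The negative control ranges overlapped while the 75th percentile differed by 1.62 log2 units, so this offset can exceed 2-fold.

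**Figure D1:**
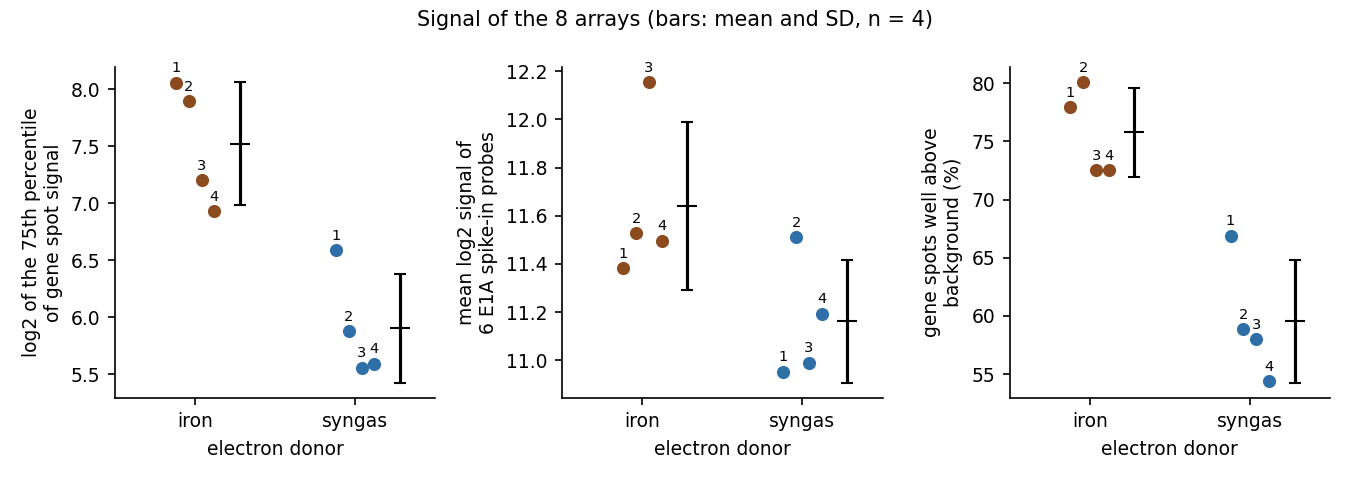
Each point is 1 array, labelled with its replicate number, and bars give the mean and SD of 4 arrays; the y axes show the log2 75th percentile of gene spot intensity, the mean log2 intensity of 6 spike-in probes and the percentage of gene spots well above background. Iron arrays lie above syngas arrays in the left and right panels without overlap, while the spike-in levels overlap.

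Cultures of a group resembled each other more than cultures of the other group. Over the 4048 measured genes, Pearson's r across genes was 0.972 to 0.995 between iron arrays, 0.921 to 0.971 between syngas arrays and 0.762 to 0.808 between the groups. The median SD within a group was 0.239 log2 units for iron and 0.344 for syngas. The first principal component separated the groups and held 78.5% of the variance, and the second, with 8.96%, spread the syngas cultures. Iron arrays 1 and 2 had the highest correlation, 0.995, and iron arrays 3 and 4 the next, 0.990.

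A large part of the measured genes differed between the iron and the syngas arrays. Of the 4048 genes, 2450 (60.5%) passed an adjusted p of 0.05 in limma, 1127 higher on iron and 1323 lower. Of these, 1632 also changed at least 2-fold: 732 were higher on iron and 900 lower. Changes of at least 8-fold were found for 79 genes higher and 176 genes lower on iron, and of at least 32-fold for 20 and 26. Some of these folds rest on signal below the lowest that was above background: with that signal as floor, 52 genes were at least 8-fold higher and 154 lower, and 12 and 26 at least 32-fold. Among all 4048 genes, without regard to the test, the 4 iron and 4 syngas values did not overlap in 2226 (55.0%), where chance gives 2.86%. The split between directions depended on scaling. With the spike-in probes as reference, the median of all genes rose by 1.09 log2 units on iron. On that scale 1753 genes were called higher and 259 lower. The rise rests on 1 offset per array, which overlapped between the groups (two-sided exact permutation p = 0.0857, n = 4 per group), so it is not established. The p-values behind these 2 counts treat genes as independent, although the offsets are shared. They also follow the size of the difference, with nearly 1 spread for all genes. Genes 09875_1917 and 01060_210, at 8.28 and -8.27, had the same limma adjusted p of 1.34e-43 on that scale. The 2 counts therefore work as a cutoff on size and not as a test of each gene. Relative to that median shift, 807 genes lay at least 2-fold above it and 863 at least 2-fold below it. With normexp background correction, whose offset sets dim genes lower on iron, 665 genes were higher and 2390 lower. Quantile normalization gave 1356 and 1129. Under these 3 settings, median scaling and the 75th percentile together, 783 genes were called the same way each time, 526 higher on iron and 257 lower. Spike-in scaling adds the same amount to every difference, so all 1127 higher calls stayed higher with it and only 258 lower calls stayed lower. The 526 and 257 therefore do not measure the balance between directions.

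**Figure D2:**
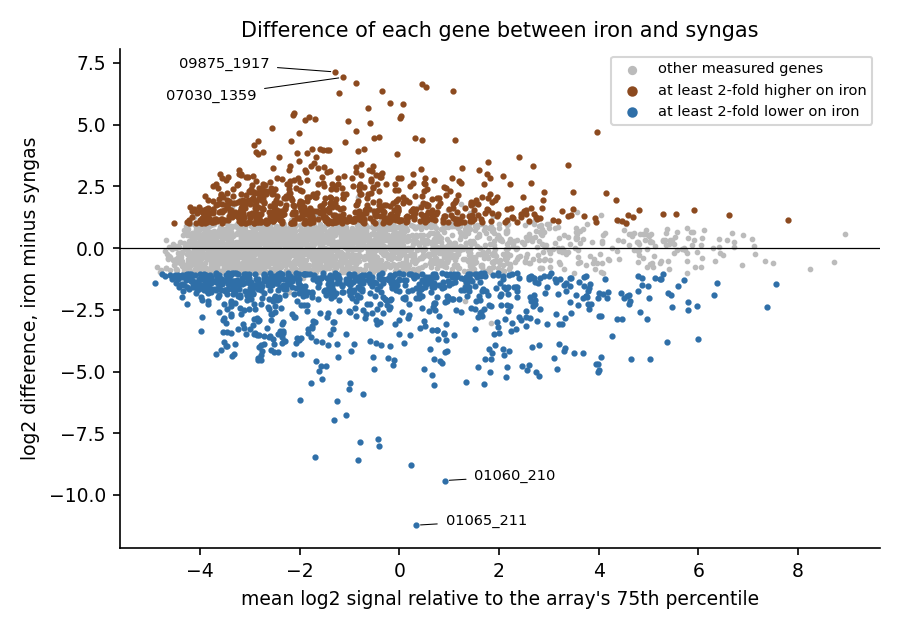
Each point is 1 of the 4048 measured genes; the x axis gives its mean log2 signal relative to the array's 75th percentile and the y axis the log2 difference, iron minus syngas. Coloured points passed an adjusted p of 0.05 in limma and changed at least 2-fold (732 higher, 900 lower); the 4 named genes are marked.

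The 2 genes with the largest fitted rises on iron were 09875_1917 and 07030_1359. Neither was above background on any syngas array, so their order and their place ahead of other genes are not resolved. For 09875_1917 the log2 signal relative to the 75th percentile was 2.28 ± 0.31 (SD, n = 4) on iron and -4.86 ± 0.41 (SD, n = 4) on syngas, a difference of 7.14 (SE 0.24, limma adjusted p = 2.37e-07). Against the lowest signal above background it was at least 39.9-fold higher on iron. Gene 07030_1359 stood at 2.33 ± 0.99 (SD, n = 4) on iron and -4.59 ± 0.47 (SD, n = 4) on syngas, a difference of 6.92 (SE 0.46, limma adjusted p = 2.16e-06). It was at least 41.3-fold higher on iron. Both bounds hold for the processed intensities only: with normexp the log2 differences were 2.85 for 09875_1917 and 3.08 for 07030_1359, which are smaller than the bounds.

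The 2 genes with the largest fitted falls were neighbours; others in their run were not above background on any iron array, so the order of falls is not resolved. Gene 01065_211 had a log2 level of 5.96 ± 1.42 (SD, n = 4) on syngas and -5.27 ± 0.86 (SD, n = 4) on iron, a difference of -11.22 (SE 0.67, limma adjusted p = 1.41e-06); it was above background on 2 of the 4 iron arrays, and with the floor the difference was -10.11. Gene 01060_210 had 5.63 ± 1.36 (SD, n = 4) on syngas and -3.78 ± 0.72 (SD, n = 4) on iron, a difference of -9.41 (SE 0.62, limma adjusted p = 2.16e-06), and was above background on all 8 arrays; with the floor the difference was -9.07. In both, syngas culture 2 was lowest of its group, at 3.91 and 3.67. All 3 probes of each of the 4 named genes moved in the direction of the gene, and the direction was kept with spike-in scaling, quantile normalization and normexp. The size was not: the differences of 01065_211 and 01060_210 were -6.70 and -6.23 with normexp, -9.91 and -8.55 with the brightest probe of each gene, and -11.90 and -10.07 without syngas culture 2.

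More genes were above background on the iron arrays only than on the syngas arrays only. All 4 iron arrays and no syngas array detected 210 genes, and all 4 syngas arrays and no iron array detected 15. The syngas arrays were also dimmer, with 59.5% against 75.8% of gene spots well above background. These counts of detected genes therefore cannot tell expression apart from array brightness. Not all of the 210 genes were called at least 2-fold higher on iron. Among the 1632 genes changed at least 2-fold, 128 were never above background in one group, 113 of them higher on iron. Another 346 were above background on only some arrays of the lower group. With the floor, the difference got smaller in 785 of the 1632 genes, and 542 were at least 2-fold higher on iron and 811 at least 2-fold lower. These last 2 counts may include genes that are dim in both groups, for which the floor gives no bound.

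Changed genes lay next to one another along the gene order. There were 88 runs of at least 4 consecutive genes that changed at least 2-fold in the same direction, against a median of 8 and a highest value of 19 in 1000 random placements of the calls (permutation p = 0.001, the smallest they can give). Of these, 34 runs with 184 genes were higher on iron and 54 runs with 369 genes were lower. Runs held 25.1% of the genes at least 2-fold higher on iron and 41.0% of those at least 2-fold lower. Runs of 8 or more genes numbered 3 among those higher on iron and 14 among those lower. Some short runs lower on iron lay near background. One of 4 genes stood at -4.69 ± 0.25 (SD, n = 4) on iron and -3.04 ± 0.13 (SD, n = 4) on syngas. Only 2 of its genes were above background on every syngas array. Part of such falls may be due to the lower background on iron. The log2 differences of adjacent genes correlated at r = 0.605 across 3499 pairs of genes, which are not independent replicates. The highest r in 1000 random orders was 0.0547. Both random references treat neighbouring genes as independent, so they speak to clustering along the gene order and not to the donor. Genes lower in syngas culture 2 than in the other syngas cultures also formed 5 runs, against a highest of 0 in 1000 random placements. The split of runs by direction depended on scaling: with quantile normalization there were 51 runs higher on iron and 39 lower, with spike-in scaling 141 and 17, and with normexp 11 and 30.

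**Figure D3:**
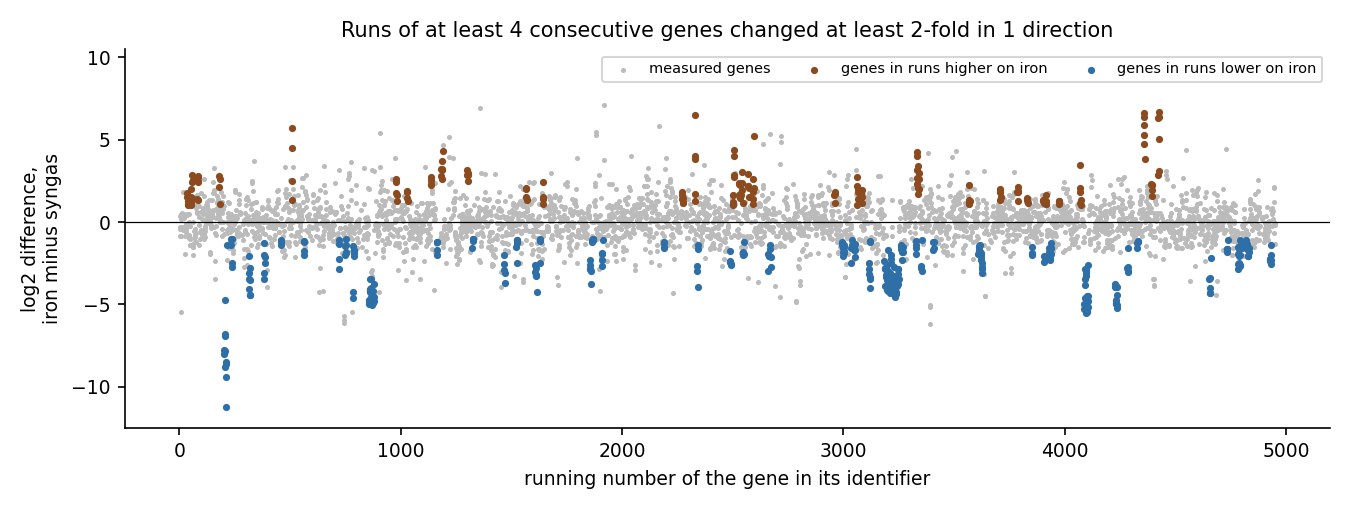
Each point is a measured gene, placed on the x axis by the running number in its identifier, with its log2 difference, iron minus syngas, on the y axis. The 184 genes in runs higher on iron and the 369 in runs lower on iron are coloured, and the deepest fall lies in the run that holds 01065_211.

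The longest runs were lower on iron. A run of 25 genes fell by 3.34 log2 units on average, from -0.75 ± 0.28 (SD, n = 4) on syngas to -4.09 ± 0.29 (SD, n = 4) on iron. All 25 genes were above background on every syngas array and 17 on every iron array. With spike-in scaling this run fell by 2.20 log2 units and with normexp it fell by 1.56. A run of 19 genes fell by 4.22 log2 units, from 2.16 ± 1.24 (SD, n = 4) to -2.05 ± 0.08 (SD, n = 4), fell by 3.07 with spike-in scaling and fell by 2.71 with normexp. A run of 18 genes was bright in both conditions, at 4.19 ± 1.13 (SD, n = 4) on syngas and 2.15 ± 0.17 (SD, n = 4) on iron. Its share of the summed gene signal was 3.45% ± 2.85 (SD, n = 4) on syngas and 0.957% ± 0.183 (SD, n = 4) on iron; it fell by 2.04 log2 units on average, fell by 1.57 without syngas culture 2 and fell by 0.90 with spike-in scaling. Of the runs of 13 genes, one fell by 1.53 log2 units, or fell by 0.39 with spike-in scaling, and the other fell by 2.06, or fell by 0.92. Under all 5 scaling and background settings, 22 of the 25 genes and all 19 of the next run were called lower, but only 4 of the 18, and 0 and 5 of the 13.

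The run with the largest mean fall held 12 genes, among them 01065_211 and 01060_210. Its fitted values fell by 7.49 log2 units on average, from 3.23 ± 1.28 (SD, n = 4) on syngas to -4.26 ± 0.31 (SD, n = 4) on iron. It took 1.33% ± 0.778 (SD, n = 4) of the summed gene signal on syngas and 0.00692% ± 0.000597 (SD, n = 4) on iron, where 5 of its 12 genes were above background on every array. With the floor it fell by 6.998 log2 units, without syngas culture 2, which stood at 1.37 against 3.52 to 4.31 in the others, it fell by 8.11, with spike-in scaling it fell by 6.35 and with normexp it fell by 4.19.

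On iron, the longest run of higher genes also had 12 members. It rose by a mean of 2.82 log2 units, from -2.03 ± 0.22 (SD, n = 4) on syngas to 0.80 ± 0.20 (SD, n = 4) on iron. Of its 12 genes, 8 were above background on every syngas array and 1 on none. The run rose by 2.54 with the floor, by 3.97 with spike-in scaling and by 1.30 with normexp. A run of 6 genes, chosen after its values were seen, had a fitted mean rise of 5.47 log2 units, from -2.99 ± 0.20 (SD, n = 4) to 2.48 ± 0.27 (SD, n = 4), with single genes between 3.85 and 6.64. Of the 6 genes, 2 were above background on every syngas array and the others on at least 2 arrays, so part of the rise is set against signal near background and the run is not ranked against others.

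Syngas cultures disagreed in some of these regions more than iron cultures did. A run of 11 genes had a mean level of 4.40 ± 3.09 (SD, n = 4) on syngas and 0.18 ± 0.67 (SD, n = 4) on iron. Syngas cultures 1, 3 and 4 stood at 5.82, 6.93 and 4.93, while culture 2 stood at -0.07, within the iron range of -0.45 to 0.77. All 11 genes passed the threshold with all 8 arrays; the run fell by 4.23 log2 units with all cultures, fell by 5.72 without culture 2 and fell by 3.38 without culture 3. In the run of 19 genes it was culture 4, at 0.42, that lay below the others, which ranged from 2.14 to 3.08.

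**Figure D4:**
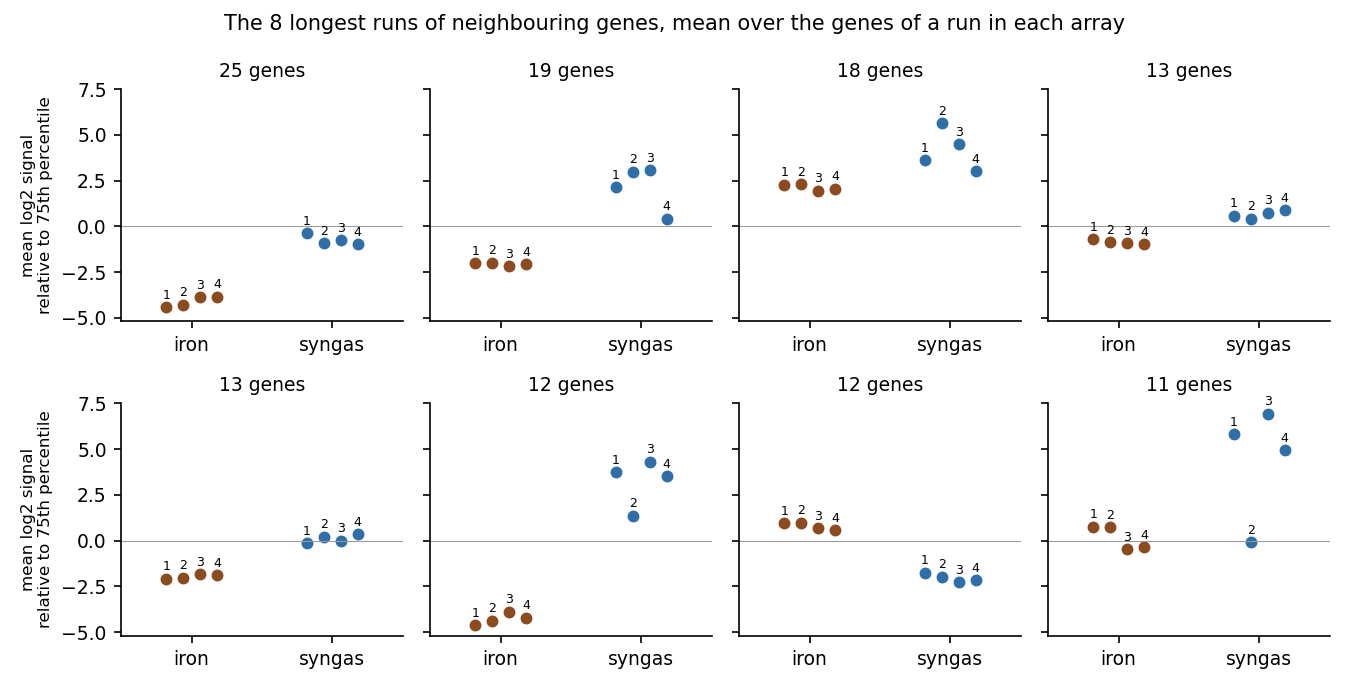
Each panel is 1 of the 8 longest runs, with the number of genes above it; points are arrays, labelled with the replicate number, and the y axis is the mean log2 signal of the run's genes relative to the array's 75th percentile. In 7 panels syngas lies above iron in the mean and in 1 panel, of 12 genes, below it; in the 11-gene run syngas culture 2 lies within the iron range.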

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

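The tests of syngas culture 2 against mixing and dim-spot noise, that of gene signal minus spike-in signal, and the splits with iron pairs averaged were chosen after the result was seen; the other tests of the iron pairs and the counts over splits of the 8 arrays were set before. Outliers were sought in 26 groups of 4 values, where chance picks out about 1 in 20 groups, and 2 were found. The gap between gene signal and spike-in signal was -4.36 log2 units on syngas array 1, apart from the other syngas arrays at -5.64 to -5.43. Gene 01060_210 stood at -2.71 on iron array 3, apart from the other iron arrays at -4.18 to -4.11. Among control probes left out of all comparisons, 1 of 13 probes of the ETG type gave a mean log2 signal 4.79 above the negative control spots, with arrays between 3.39 and 5.74.

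No other division of the arrays gave what the real one gave. Of the 35 splits of the 8 arrays into 4 and 4, 1 called as many genes as iron against syngas, namely the real split with 2450 genes; the highest of the others called 0. For runs of neighbouring genes, 1 of the 35 splits, the real one with 88, reached that number, and the highest other had 0. For 4 separate iron cultures, as the design states, 1 in 35 is a share under 0.05, and it is the smallest these splits can give. Chance division of the arrays is thus unlikely but not excluded, and a difference that follows the slide row is not addressed. The other splits mix the groups, which widens the spread within each side, so their 0 calls say little on their own. With each close pair of iron arrays averaged, the real split gave 1864 genes and 80 runs and the highest other gave 0 of either, but the 15 splits are too few for a share under 0.05.

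Gene signal was lower relative to the spike-ins on the syngas arrays. The difference, iron minus syngas, was 1.14 log2 units, with overlap between the groups (two-sided exact permutation p = 0.0857, n = 4 per group). A dimmer hybridisation or scan would lower genes and spike-ins alike and leave no such difference, but with the overlap between arrays the pattern cannot be told apart from it. Slide rows with arrays of both groups numbered 0, so row and donor cannot be told apart either. Unequal amounts of spike-in RNA between samples, and a lower share of messenger RNA in total RNA of syngas cultures, stay open and were not tested.

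Iron cultures 1 and 2, and 3 and 4, formed close pairs. The SD between arrays over probes of like brightness was 0.155 and 0.184 log2 units within the pairs and 0.290 to 0.350 between them. In the brightest of 4 equal classes of genes the median absolute difference was 1.94 times as large between pairs as within, which argues against weak array signal as the whole cause. The SD within a pair was at least 1.85 times that between repeated spots of 1 array. That bound had been set to exclude a single labelled RNA on both arrays, but repeated spots leave out the noise between hybridisations, so this stays open. No biological explanation was tested, since the labels give no group to these pairs.

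Stretches of neighbouring genes were lower in syngas culture 2 than in the other syngas cultures. It lay over 2 log2 units below their mean in 61 genes, 38 of them in runs of at least 4 with a median gap of -5.26, and above it by as much in 59 genes. Such deviations were not particular to this culture: syngas culture 4 lay as far below the others in 66 genes and above in 37, and formed 7 runs of either direction against 8 in culture 2. Those of culture 4 were not tested. Iron RNA mixed into syngas culture 2 would need to make up most of its RNA. Yet the 79 genes at least 8-fold higher on iron stayed a median of 3.84 log2 units below the iron level in it. Culture 2 was among the arrays that picked these 79 genes, so part of that distance is set by the pick. Noise of dim spots would need the 61 lower genes to be dim. Yet 90.2% of them were above background on all 4 syngas arrays, which argues against such noise as the whole cause. A difference in the state of the cultures may account for the pattern and was not tested.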

How the results depend on the processing

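The 4 named genes kept their direction and stayed past the threshold in every setting in which they were tested, but not their size: normexp gave 2.85, 3.08, -6.70 and -6.23 in place of 7.14, 6.92, -11.22 and -9.41, and the brightest probe gave -9.91 and -8.55 for the last 2. Of the 4, 3 do not pass the strictest filter. With the replicate block, 2346 genes were called and 88 became 90 runs; deviations of same-numbered iron and syngas arrays from their group means correlated at 0.14, -0.13, -0.13 and -0.0014 across genes, and no array correlated best with its own number. Leaving out 1 array at a time gave 2208 to 2432 genes called, with 146 to 256 of the 2450 calls lost and 0 changes of sign, and 85 to 92 runs. Averaging the close pairs of iron arrays called 1864 genes. Normexp changed the spot intensity used, the background method and the offset (50) together. It gave 665 genes higher, 2390 lower and 827 changed 2-fold (282 higher, 545 lower). There were 41 runs (11 higher, 30 lower), and the median of all genes was -0.52. An offset of this size shrinks the folds of dim genes and, after scaling, sets them lower on iron. How much of these shifts it accounts for was not separated. Requiring signal above background on all 8 arrays tested 2745 genes: 694 were higher, 395 of them 2-fold, and there were 50 runs, 13 higher. Quantile normalization turned the split, with 1356 genes higher and 1129 lower, and 51 runs higher and 39 lower. No filter gave 3078 calls, 1133 higher (36.8%) and 1945 lower. The calls gained were thus almost all lower on iron, where background lies lower on the scaled values. The median of all genes moved to 0.13 with quantile normalization, -0.29 with no filter and -0.17 with the strictest filter. Spike-in scaling called 1753 higher and 259 lower, all at least 2-fold, with 158 runs (141 higher, 17 lower). It adds 1.14 log2 units to every difference. Array offsets shared by all genes enter its spread, so its p-values assume an independence between genes that is not there. They also rest on nearly 1 spread for all genes, so its calls work as a cutoff on the size of the difference. A test against 1.5-fold called 1350 genes, 605 higher and 745 lower. Runs of at least 3 genes numbered 153 (63 higher, 90 lower) and of at least 5 genes 55 (21 higher, 34 lower). Of the values tied to the comparisons, 159 stayed within 1.5 times and 28 did not; the cause was not tested except where the setting itself tests fewer genes. No setting could be run for the pathway lists. Signal over background limits folds: against the floor the difference got smaller in 454 of the 732 genes at least 2-fold higher on iron and in 331 of the 900 lower.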

Other observations

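Co-change of genes reached beyond direct neighbours. The correlation of log2 differences across genes was 0.605 at a distance of 1 gene, 0.439 at 2, 0.244 at 5, 0.0947 at 10 and 0.0451 at 20, and adjacent genes had the same sign in 68.4% of pairs against 49.8% at a distance of 100. With genes in 4 equal classes by signal, falls on iron outnumbered rises in the brightest, 39.6% against 25.3% of its 1012 genes, and in the dimmest, 32.7% against 21.9%. In the classes between, falls and rises were 29.9% and 33.5% in the brighter and 28.5% and 30.6% in the dimmer. Signal at background lies lower on iron on this scale, so part of the falls among the dimmest genes may be due to that offset. Of the 3 genes of the separate sequence, 2 were measured. One fell by 1.31 log2 units on iron (SE 0.18, limma adjusted p = 0.00022), and the other differed by -0.42 (SE 0.19, limma adjusted p = 0.0815).

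By size of deviation, the syngas cultures, whose spread was larger, stood out. Genes over 2 log2 units from the mean of the other 3 syngas cultures formed 8 runs in culture 2, 7 in culture 4, 2 in culture 3 and 1 in culture 1, and 0 in each iron culture. Each iron array was set against a mean that holds its close partner, which shrinks its deviation. A split between the iron pairs is thus hard to see by either measure used here. Gene 07030_1359, for example, stood at 1.54 and 1.40 on iron arrays 1 and 2 and at 3.13 and 3.24 on 3 and 4. Measured against the range of its own group (Dixon's ratio), iron culture 4 had the most outlying genes, 73 or 1.80%. The other iron cultures had 22 to 45, against 38 to 67 in the syngas cultures. Chance picks out about 1 in 20 groups of 4 values, so over 4048 genes many such cases arise by chance. The counts were not tested against that share and are not read as a trait of any culture. Of the 61 genes lower in syngas culture 2, 59.0% were also called lower on iron, against 32.3% of the other measured genes. That culture enters the comparison with iron, so these shares are not independent.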
